A study of Homo sapiens with 2 samples.

How the data were processed

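Gene expression was measured by RNA sequencing in 2 libraries, 1 from wild-type H1 human embryonic stem cells and 1 from H1 cells labelled as MEIS1 deleted. Per the labels, cells received 40 ng/ml activin A and 50 ng/ml BMP4 for 2 days and then 40 ng/ml VEGF and 50 ng/ml bFGF for 2 days, and were collected at day 3, which falls within the second step. Libraries were made from 2 µg of total RNA with an Illumina TruSeq RNA kit, per the labels' protocols. The labels did not state separate cultures or clones, the deleted part of MEIS1, or whether the kit kept strand.

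The deposited tables held, for each gene with at least 1 read fraction assigned, a gene number, transcripts, a length, an expected count and an FPKM value, per the file headers. Expected counts are estimated counts that need not be whole, because reads that fit several genes are divided between them, and the authors deposited them without scaling. The deposited FPKM values are scaled for gene length and library depth. The submitters' processing notes named BWA, Bowtie, RSEM and the human build hg19 without versions, and the column layout was that of RSEM. The series design text named BWA with an analysis of variance and TopHat with Cufflinks, and which of these steps preceded the tables was not given in the sources used here. Genes listed in 1 table alone were taken as 0 in the other, which applied to 822 genes in the wild-type table and 956 in the other, with expected counts of at most 76.9 and 52.7.

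Gene numbers were matched to symbols through a RefSeq gene table of assembly GRCh38.p14, used for names and for the chromosome of a gene. No result given here rests on its coordinates, because the files used another build. Of 18518 gene numbers, 18413 matched and 105 did not. Unmatched numbers held 0.181% of the wild-type counts and 0.193% of the counts in the library labelled deleted. Expected counts were whole, within 0.005, for 69.4% and 69.9% of listed genes, and all were rounded to whole numbers before use. Totals were 5202847 and 5296397 after rounding, with a median of 89 and 86 counts per listed gene and 13907 and 13951 genes at 10 counts or more. At this depth a gene with no count could hold up to 3 counts, and intervals and this floor cover counting error only, since reads copied by PCR are not independent molecules.

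Counts were scaled by TMM effective library sizes from edgeR 4.0.16 in R 4.3.3, which differed by a factor of 1.01 between the libraries. Log2 ratios used a pseudocount of 1 on the count. Folds are those ratios as linear values, and each has an exact Clopper-Pearson 95% interval computed from the counts without a pseudocount, conditional on their sum. With 1 library per genotype, no model was fitted, no test between genotypes was run and no replicate check was possible. Genes with at least 10 counts in 1 library or more were compared, and a gene was counted as at least 2-fold higher or lower when its ratio reached that size and its interval excluded 1. In text, a list member is called higher or lower when its counting interval excluded 1.

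The following choices were made before the data were examined: the rules above, the gene lists, the rule for named genes and the alternatives. There were 34 lists, covering pluripotency, primitive streak and nascent mesoderm, lateral plate and extraembryonic mesoderm, cardiac mesoderm, paraxial and intermediate mesoderm, haemato-endothelial transcription factors, endothelial markers, blood cell markers, the arterial and Notch pathway, MEIS and PBX family genes, the HOXA cluster, the HOXB cluster, definitive endoderm, neural and surface ectoderm, amnion and trophoblast, fibroblast and smooth muscle, both sides of the epithelial to mesenchymal transition, BMP and SMAD targets, Nodal and activin targets, canonical WNT targets, FGF and ERK targets, the VEGF pathway, hypoxia, glycolysis, cholesterol synthesis, S phase, G2 and M phase, p53 targets, the unfolded protein and amino acid stress response, immediate early genes, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation and housekeeping reference genes. Each list's median log2 ratio was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins, and a list stood apart when its percentile was under 2.5 or over 97.5, which describes these libraries. Placing members with 0 counts in 1 library at their bounds moved no list median.

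Named genes were MEIS1, the regulators TAL1, FLI1, RUNX1, GATA2, LMO2 and ETV2, and the 10 genes with the largest ratios in each direction among those with at least 200 counts in 1 library, small RNAs, unnamed loci symbols, Y-linked genes and XIST excepted. The rule further took up to 4 members of each list with the largest absolute ratios among members with at least 50 counts, of which the text gives a part. Genes outside this rule are marked in the text as chosen after their values were seen.

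The computation was tested on simulated counts for 18518 genes drawn from the means and sizes of both libraries, with 50 genes changed at each fold. The 2-fold rule called 4% of genes with a true fold of 1.5, 44% at a true fold of 2, 98% at 4 and 100% at 8, and 66 of 14093 unchanged genes were called. Intervals covered the true ratio for 95.9% of unchanged genes, and 2 of 100 unshifted lists stood apart. The simulation held counting error alone, so differences between cultures are not in these rates.

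Alternatives were DESeq2 1.42.0 size factors, total counts and upper quartile scaling, FPKM with a pseudocount of 1 and a minimum of 1, pseudocounts of 0.1 and 5, minimum counts of 1 and 50, the deeper library thinned to the depth of the other, fold rules of 1.5 and 4, random lists not matched on expression, and list means in place of medians. Tables were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.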

Results

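RNA was sequenced from H1, an established human embryonic stem cell line, and from H1 cells labelled as MEIS1 deleted, both collected at day 3 of differentiation towards blood. MEIS1 encodes a homeodomain transcription factor of the TALE class that works with HOX and PBX proteins. The data held 1 library per genotype. The wild-type library listed 17562 genes with 5202875 estimated counts, and the library labelled deleted listed 17696 genes with 5296440. FN1, which encodes the matrix protein fibronectin, had the highest count in both, with 1.17% and 1.29% of all counts. Ribosomal RNA took 0.0692% of the wild-type counts (exact 95% binomial interval 0.067 to 0.0715) and 0.149% of those in the library labelled deleted (0.145 to 0.152). With no replicates there was no test between genotypes, so every difference compares these 2 libraries and not the genotypes in general. Ratios carry exact 95% intervals that cover counting error only.

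The comparison asked how gene expression at day 3 differed when MEIS1 was deleted. MEIS1 itself (gene 4211 in the files) had 89 counts in the wild-type library and 68 in the library labelled deleted, or 5.34 and 4.01 FPKM. Its level in the latter was 0.758 of wild type (0.542 to 1.05), a log2 ratio of -0.40 (-0.88 to 0.07), so the interval included no difference. The files gave a single value per gene and did not show which part of MEIS1 the reads came from, and the labels did not say which part was deleted. The genotype labels could therefore not be checked against the MEIS1 level, and every direction below is that of the library labelled deleted.

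Regulators of blood and endothelium were mostly higher in the library labelled MEIS1 deleted, and primitive streak and pluripotency genes were mostly lower. GATA2, needed for blood stem and progenitor cells, had 256 counts in wild type and 688 in the library labelled deleted, 2.65-fold higher (2.30 to 3.08). RUNX1, needed for blood cells to arise from endothelium, was 2.40-fold higher (1.92 to 3.04), LMO2 2.14-fold (1.77 to 2.61), FLI1 2.04-fold (1.75 to 2.39) and TAL1, a master regulator of blood formation, 1.75-fold (1.46 to 2.10). ETV2, an early and transient inducer of endothelial and blood fate, went the other way, with 72 counts in wild type and 14 in the library labelled deleted, 4.93-fold lower (2.91 to 9.99). EOMES, a T-box factor of the primitive streak, was 4.14-fold lower (3.57 to 4.86), with 867 and 211 counts.

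**Figure D1:**
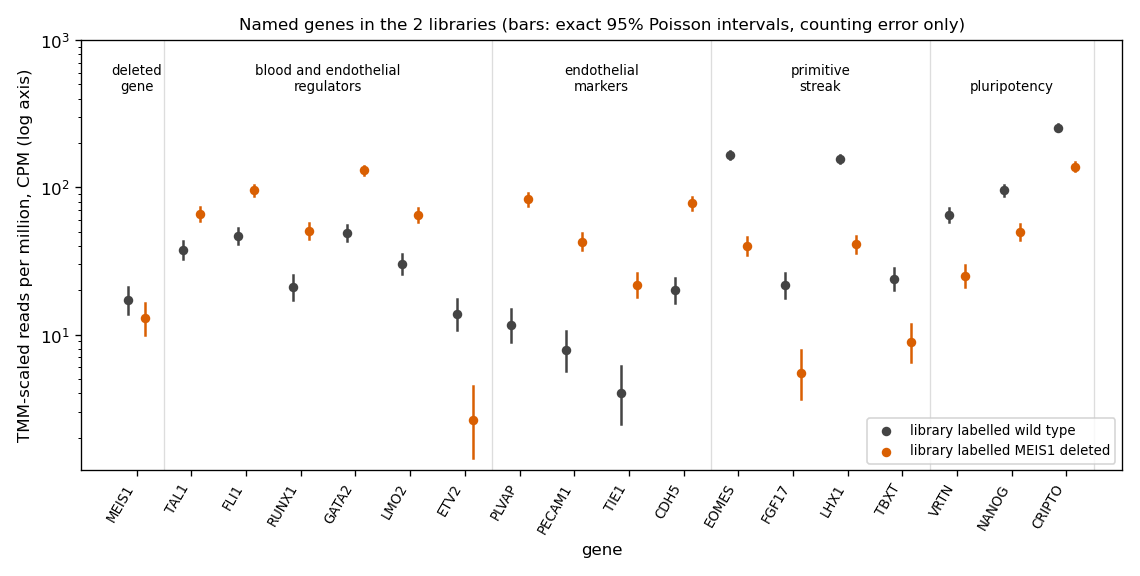
TMM-scaled read abundance (CPM) on a log axis for MEIS1, 6 regulators of blood and endothelium, 4 endothelial markers, 4 primitive streak genes and 3 pluripotency genes in the library labelled wild type (grey) and the library labelled MEIS1 deleted (orange). Points are the single library of each genotype and bars are exact 95% Poisson intervals for counting error; the MEIS1 intervals overlap, whereas GATA2 had 256 and 688 counts and EOMES 867 and 211.

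Among the 20 measured transcription factors of the haemato-endothelial list, 13 had an interval above a ratio of 1, 2 an interval below it and 5 an interval that included it. At least 2-fold differences were seen for 10 members in the higher direction and 1, ETV2, in the lower. The list median was 0.96 on the log2 scale, above each of 10000 random lists of matched expression (percentile 100). GFI1, a repressor that acts in the transition from endothelium to blood, had 53 and 139 counts and was 2.56-fold higher (1.88 to 3.63).

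Endothelial markers followed the same direction. Of 25 measured, 17 were higher, 2 lower and 6 had an interval that included 1, and 10 were higher by at least 2-fold, with a median log2 ratio of 0.77 (percentile 100). PLVAP, a protein of endothelial fenestrae, had 61 and 437 counts and was 6.98-fold higher (5.41 to 9.41). PECAM1 (CD31), an endothelial junction protein, was 5.34-fold higher (3.89 to 7.79), the receptor gene TIE1 5.21-fold (3.38 to 9.07) and CDH5 (VE-cadherin) 3.87-fold (3.13 to 4.88). On the FPKM scale with a pseudocount of 1, which understates low genes, the log2 ratios of PECAM1 and TIE1 were 1.76 and 1.68. The VEGF pathway list had a median of 0.30 (percentile 99.8), with 8 of 13 members higher and 5 with an interval that included 1. Several of its members, higher ones among them, also belong to the list of endothelial markers and were counted in both. FLT1, which encodes a VEGF receptor, had 4347 and 7523 counts, 1.71-fold higher (1.65 to 1.78). In the arterial and Notch pathway list 8 of 16 members were higher, 4 lower and 4 included 1 (median 0.31, percentile 99.97). The Notch ligand gene JAG2 was 2.77-fold higher (1.78 to 4.68) and the receptor gene NOTCH3 1.44-fold lower (1.32 to 1.59), and from FPKM the log2 ratio of JAG2 was 0.86 and the median of this list -0.017 (percentile 47.4).

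Blood cell markers as a list did not stand apart by their median. Of 25 symbols, 9 were listed in neither library and 6 were below the minimum, and the 10 measured had a median of 0.24 (percentile 93.0), with 2 higher, 1 lower and 7 that included 1. The list did stand apart by its mean (0.65, percentile 99.0) and against random lists not matched on expression (percentile 97.6). MMRN1, an endothelial and platelet gene from the endothelial list, had 0 counts in wild type and 32 in the library labelled deleted, at least 10.5-fold higher against a floor of 3 counts in the wild-type library when the 32 counts are taken as exact. The lower limit of its counting interval, which allows for error in both, was 3.02 on the log2 scale. MMRN1 was chosen after its values were seen.

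Primitive streak and nascent mesoderm genes were mostly lower in the library labelled deleted. Of 13 measured members 11 were lower, 1 higher and 1 had an interval that included 1, and 9 were lower by at least 2-fold. The list median was -1.41, below each of the random lists (percentile 0). LHX1, a factor of the streak and its derivatives, was 3.77-fold lower (3.26 to 4.42), FGF17 3.85-fold (2.60 to 6.15) and TBXT (Brachyury) 2.66-fold (1.91 to 3.85), with 125 and 47 counts. Pluripotency genes had a median of -0.54 (percentile 0), with 12 of 18 lower, 6 that included 1 and 0 higher. VRTN was 2.59-fold lower (2.12 to 3.20), NANOG 1.92-fold (1.65 to 2.24) and CRIPTO, the NODAL co-receptor gene also called TDGF1, 1.84-fold (1.68 to 2.02).

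The lists of Nodal, WNT, FGF and BMP target genes had medians below the range of random lists. The Nodal and activin targets, several of which also belong to the lists of pluripotency and primitive streak genes, had a median of -0.86 (percentile 0), with 5 of 8 lower, 1 higher and 2 that included 1. CER1, a secreted inhibitor of NODAL, BMP and WNT, was 4.33-fold lower (2.99 to 6.79), with 136 and 31 counts. Canonical WNT targets had a median of -0.44 (percentile 0.01), with 6 of 12 lower, 1 higher and 5 that included 1, and SP5 was 2.17-fold lower (1.67 to 2.87). FGF and ERK targets had a median of -0.25 (percentile 0.03), with 8 of 14 lower and 6 that included 1, and the feedback inhibitor gene SPRY4 was 1.99-fold lower (1.85 to 2.15). BMP and SMAD targets had a median of -0.21 (percentile 0.42), with 5 of 13 lower, 3 higher and 5 that included 1, and ID4 was 1.92-fold lower (1.67 to 2.23). The position of the BMP and SMAD list was lost with its mean in place of its median (percentile 4.05) and against random lists not matched on expression (3.25).

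The medians of the mesoderm lists differed in direction by subtype. Cardiac mesoderm genes had a median of 0.49 (percentile 100), with 7 of 13 higher, 3 lower and 3 that included 1. MEF2C was 4.22-fold higher (2.87 to 6.72), the heart and limb factor gene HAND2 4.14-fold (3.17 to 5.60) and NKX2-5 2.02-fold (1.43 to 2.93). From FPKM the log2 ratio of MEF2C was 1.34, against 2.08 from counts. Lateral plate and extraembryonic mesoderm genes had a median of 0.19 (percentile 99.0), with 8 of 17 higher, 4 lower and 5 that included 1, and the mean of the list, 0.071, did not stand apart (percentile 68.8). FOXF1 was 2.03-fold higher (1.57 to 2.67) and ALCAM 1.69-fold (1.57 to 1.83), whereas BMP2 was 1.85-fold lower (1.64 to 2.08). Paraxial and intermediate mesoderm genes had a median of -0.75 (percentile 0.63), with 2 of 6 lower and 4 that included 1, and FOXC1 was 1.91-fold lower (1.19 to 3.26). The paraxial median rested on few genes, since of 16 symbols 4 were listed in neither library and 6 were below the minimum.

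The HOX and TALE genes, partners and relatives of MEIS1, differed by group. MEIS2, a close relative of MEIS1, had 136 and 290 counts and was 2.10-fold higher (1.71 to 2.60) in the library labelled deleted. Over the list of MEIS and PBX family genes the median was -0.11 (percentile 12.9), with 1 of 9 higher, 4 lower and 4 that included 1. HOXB genes had a median of 0.30 (percentile 99.6), with 4 of 8 higher and 4 that included 1, and HOXB9 was 1.499-fold higher (1.33 to 1.70). HOXA genes had a median of 0.59 (percentile 99.0), with 2 of 6 higher, 1 lower and 3 that included 1, and HOXA9 was 3.07-fold higher (2.02 to 5.05) on 27 and 86 counts. With genes of 1 count or more let in, the HOXA median was 0.068 (percentile 65.4).

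Markers of other cell types that such cultures can hold moved in both directions. Definitive endoderm genes had a median of -0.17 (percentile 5.92) and a mean of 0.0019, with 3 of 17 higher, 4 lower and 10 that included 1. CER1, given above, was 4.33-fold lower, and the apolipoprotein gene APOA1 was 2.87-fold higher (2.24 to 3.76). The endoderm median was -0.31 (percentile 0.42) among members with at least 50 counts and 0.0034 (percentile 58.1) from FPKM. Neural and surface ectoderm genes had a median of -1.04 (percentile 0.065), with 2 of 5 lower and 3 that included 1, and OTX2 was 2.33-fold lower (1.83 to 3.01). This rested on few genes, and with genes of 1 count or more let in the median was -0.052 (percentile 27.1). Amnion and trophoblast genes had a median of 0.21 (percentile 98.0), with 4 of 12 higher, 4 lower and 4 that included 1. IGFBP3 was 3.68-fold higher (3.18 to 4.32) and TFAP2C 2.04-fold lower (1.78 to 2.36), and among members with at least 50 counts the median of the amnion list turned to -0.32 (percentile 0.32). Fibroblast and smooth muscle genes had a median of 0.21 (percentile 99.7), with 8 of 17 higher, 3 lower and 6 that included 1, and from FPKM the median was 0.12 (percentile 94.7). The collagen gene COL3A1 was 7.12-fold higher (6.37 to 8.01) and COL6A3 4.89-fold (4.22 to 5.73), while POSTN (periostin) was 1.94-fold lower (1.76 to 2.15). Epithelial genes of the epithelial to mesenchymal transition had a median of -0.33 (percentile 0.08), with 4 of 15 lower and 11 that included 1, and the tight junction gene CLDN6 was 1.64-fold lower (1.496 to 1.79). With a minimum of 50 counts the epithelial median was -0.18 (percentile 3.1). Mesenchymal genes of the transition had a median of 0.020 (percentile 48.7) and a mean of -0.063, with 7 of 15 higher, 4 lower and 4 that included 1, and SNAI1 (Snail) was 2.20-fold lower (1.61 to 3.09).

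Growth and metabolism lists differed by little. S phase genes had a median of 0.18 (percentile 99.8), with 9 of 20 higher and 11 that included 1, and G2 and M phase genes 0.070 (percentile 87.1), with 4 of 20 higher and 16 that included 1. Cytosolic ribosomal protein genes had a median of 0.13 (percentile 98.9), with 19 of 27 higher, and nuclear-encoded oxidative phosphorylation genes 0.16 (percentile 99.1), with 8 of 19 higher. Against random lists not matched on expression these medians lay at percentiles 95 and 96.1. Glycolysis genes had a median of -0.11 (percentile 1.38), with 8 of 17 lower, 6 higher and 3 that included 1, and PKM, which encodes pyruvate kinase, was 1.37-fold lower (1.33 to 1.41). The glycolysis mean lay at percentile 18.1. Medians inside the random range were found for hypoxia (0.069, percentile 81.6), cholesterol synthesis (0.076, 80.7), p53 targets (0.046, 71.7, with a mean of -0.022), the unfolded protein and amino acid stress response (-0.10, 5.27), immediate early genes (-0.15, 5.92) and housekeeping reference genes (-0.063, 11.6, with a mean of 0.053). The immediate early gene FOS was 2.02-fold lower (1.34 to 3.22) and the reference gene HPRT1 1.82-fold higher (1.36 to 2.49), the latter on 70 and 130 counts.

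**Figure D2:**
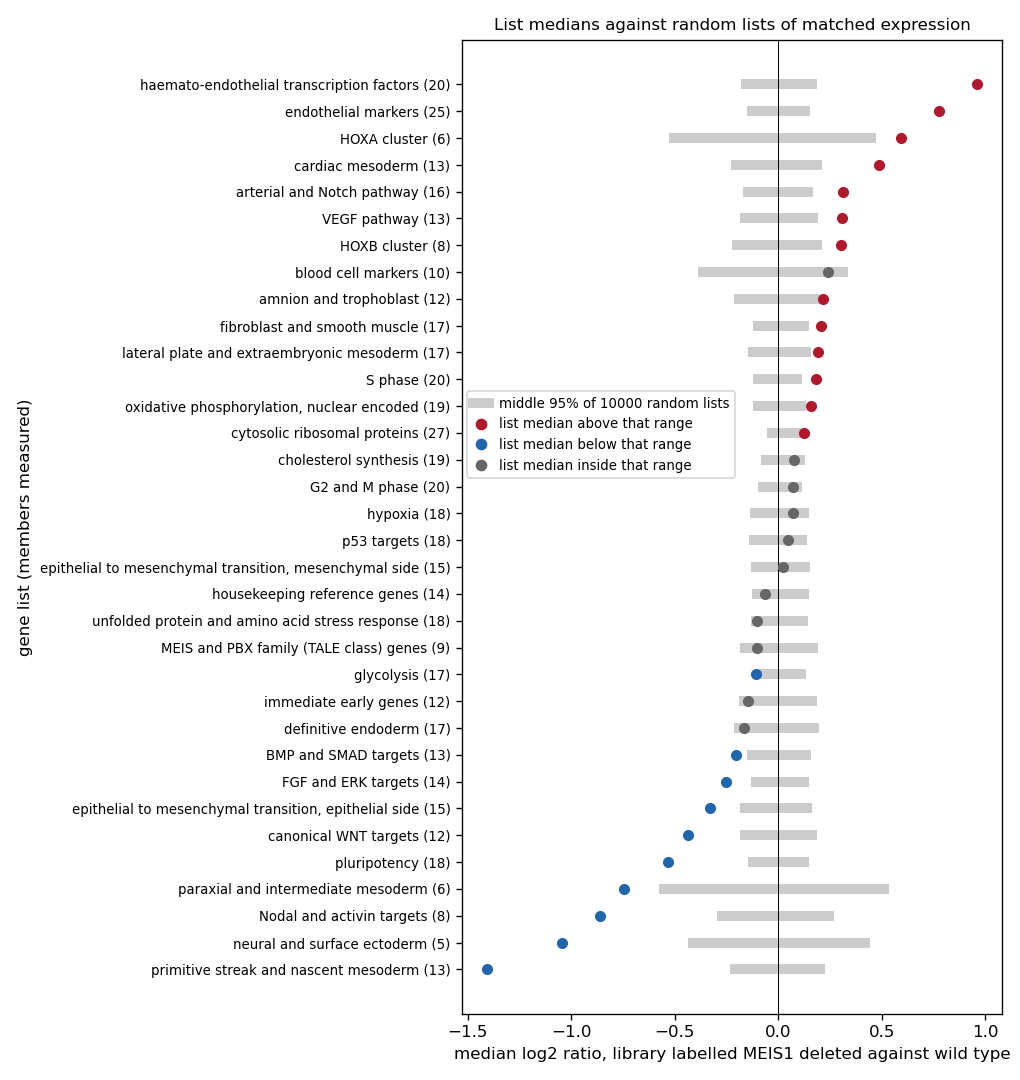
Median log2 ratio of the library labelled MEIS1 deleted against wild type (horizontal axis) for 34 gene lists (vertical axis, measured members in parentheses); points are list medians and grey bars the middle 95% of 10000 random lists of matched expression. Of the lists, 13 lay above that range, 10 below it and 11 inside it, from -1.41 for primitive streak genes to 0.96 for haemato-endothelial transcription factors.

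Of the 34 lists, 13 stood apart in the higher direction and 10 in the lower, where 1.7 would do so by chance if lists were independent, which lists with shared genes are not. Across 14381 genes with at least 10 counts in 1 library or more, 417 (2.90%) were at least 2-fold higher in the library labelled deleted and 424 (2.95%) at least 2-fold lower, each with an interval that excluded 1. A minimum count of 50 left 161 and 171 of them. From FPKM, where no counting interval was needed, 179 of the higher and 179 of the lower genes were called again. Differences were small for most genes, 82.6% of which lay within 1.5-fold. The counting interval alone excluded 1 for 2193 genes in the higher direction and 2143 in the lower.

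Among genes with at least 200 counts in 1 library, the 10 with the largest ratios in the higher direction included COL3A1, PLVAP, PECAM1, COL6A3, HAND2 and CDH5, described above. LAPTM5, a lysosomal membrane gene of blood cells, was 4.50-fold higher (3.40 to 6.22) and SAMSN1, an adaptor gene of blood cells, 4.24-fold (3.38 to 5.46). PECAM1, TMX2-CTNND1 and gene 414216 had expected counts that were not whole (40.52 and 226.26 for PECAM1), so they shared reads with other genes and their ratios were uncertain. Of the genes given above, TAL1, FLI1, VRTN, NANOG, CRIPTO, HOXA9, CLDN6, SP5 and FLT1 also had a count that was not whole within 0.005. TMX2-CTNND1, a readthrough transcript, was 5.23-fold higher (4.12 to 6.85), but its counts summed with those of CTNND1 gave a log2 ratio of -0.28 (-0.36 to -0.21). Gene 414216, for which no symbol was found, had 1 and 213 counts, 106-fold higher (37.4 to 8352), and the pseudogene BMS1P2 mirrored it with 214 and 1 counts, 109-fold lower (38.5 to 8594). From FPKM, where a pseudocount of 1 weighs more, their log2 ratios were 3.22 and -3.21.

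After BMS1P2, the genes with the largest ratios in the lower direction included EOMES and LHX1, given above, and SHISA3, a gene of a family of WNT and FGF signalling inhibitors, which was 5.32-fold lower (4.13 to 7.11). SHISA6 was 4.21-fold lower (3.43 to 5.27), ARHGAP40 3.92-fold (2.93 to 5.48) and the neurofilament gene NEFM 3.38-fold (2.84 to 4.08). NTS, the gene of the peptide neurotensin, had 4065 and 1298 counts and was 3.17-fold lower (2.98 to 3.38), COL13A1 3.06-fold (2.43 to 3.94) and CYP26A1, which encodes a retinoic acid-degrading enzyme, 3.05-fold (2.60 to 3.62).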

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

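All alternatives here were chosen before the data were examined. MEIS1 kept its direction and stayed within its main counting interval, which included 1, in 7 of 7 alternatives. For single named genes, 458 of 469 values stayed within their counting interval and the other 11 kept their sign. The counts of genes at least 2-fold higher and lower stayed within 1.5 times of 417 and 424 in 8 of 11 alternatives each. They were 161 and 171 with a minimum count of 50, where fewer genes were compared, 825 and 899 at 1.5-fold, and 111 and 81 at 4-fold. FPKM gave 319 and 314 genes, of which 179 and 179 were among those called from counts. The FPKM calls followed another rule, with a minimum of 1 FPKM, a pseudocount of 1 and no counting interval. How much of the mismatch came from this rule was not tested. With a minimum count of 50, the HOXA cluster and the paraxial and intermediate mesoderm list kept too few members for a value. Of the 372 alternative list values computed, 349 kept their side of the threshold, 18 lost the call, 3 gained it and 2 reversed. Of the 349, 6 changed sign without standing apart: definitive endoderm to 0.0034 from FPKM, 0.0080 with a minimum count of 1 and 0.0019 by mean, and by mean the mesenchymal side of the transition (-0.063), p53 targets (-0.022) and housekeeping genes (0.053). The cause was not tested unless named. From FPKM the arterial and Notch pathway median reversed to -0.017 (percentile 47.4), and amnion and trophoblast gave 0.16 (95.7), fibroblast and smooth muscle 0.12 (94.7) and cytosolic ribosomal proteins 0.12 (94.0). A minimum count of 50, which left fewer members, reversed amnion and trophoblast to -0.32 (0.32), gave the epithelial side of the transition -0.18 (3.1) and brought definitive endoderm to -0.31 (0.42, now apart). A minimum count of 1, which let in members with few reads, gave HOXA 0.068 (65.4) and neural and surface ectoderm -0.052 (27.1). A pseudocount of 5 gave amnion and trophoblast 0.18 (96.8), and thinning gave glycolysis -0.096 (2.75). Against random lists not matched on expression the same medians lay inside the range for amnion and trophoblast (0.21, 97.3), BMP and SMAD targets (-0.21, 3.25), glycolysis (-0.11, 11.3), cytosolic ribosomal proteins (0.13, 95) and oxidative phosphorylation (0.16, 96.1), and outside it for blood cell markers (0.24, 97.6). Means in place of medians gave lateral plate and extraembryonic mesoderm 0.071 (68.8), HOXA 0.50 (96.3), BMP and SMAD targets -0.22 (4.05), glycolysis -0.053 (18.1), cytosolic ribosomal proteins 0.12 (96.0) and blood cell markers 0.65 (99.0, now apart). Scaling moved log2 ratios by at most 0.0085. No paired analysis was possible because there was 1 library per genotype, which also left no library that could be taken out. Depth limited genes with few reads, such as MEIS1, whose fold interval ran from 0.542 to 1.05 on 89 and 68 counts.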

Other observations

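In this part the tests of GC content with gene length and of shared reads as the source of most 2-fold calls were set before their results were seen, and all other tests, and the genes and families of the next 2 paragraphs, were chosen after the values were seen.

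Collagen genes did not move together. Chains of collagen VI that assemble into a joint molecule went apart. COL6A1 was 1.78-fold lower in the library labelled MEIS1 deleted (3337 and 1895 counts) and COL6A2 1.19-fold lower (1378 and 1170), while COL6A3 was 4.89-fold higher (205 and 1019). A further collagen VI gene, COL6A6, was 1.54-fold lower on 60 and 39 counts. The basement membrane genes COL4A1 and COL4A2 were 1.46-fold and 1.65-fold higher, on 6574 and 9715 counts and on 3923 and 6557, and COL1A1 was 1.72-fold higher. RSPO2 and RSPO3, whose secreted products strengthen WNT signalling, were 2.96-fold higher (312 and 935 counts) and 2.73-fold higher (146 and 405), although canonical WNT targets as a list had a median of -0.44.

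Gene families defined by shared symbol stems were placed among random lists in the same way. Of 251 families with at least 8 measured genes, 6 lay in the lowest 0.5% of random lists and 8 in the highest 0.5%, where 2.51 in both tails together would by chance if families were independent, which related genes are not. WNT genes had a median of -0.72 (5 of 8 lower), semaphorin genes (SEMA) -0.32 (10 of 20 lower, 3 higher) and calcium channel genes (CACNA) -0.73 (3 of 8 lower). The other CACNA genes had at most 29 counts in either library and intervals that included 1. On the higher side were CDKN genes, mostly inhibitors of the cell cycle, at 0.43 (6 of 9 higher), the chaperonin genes (CCT) at 0.29 (7 of 9 higher), integrin alpha genes (ITGA) at 0.35 (4 of 12 higher, 2 lower) and large-subunit ribosomal protein genes (RPL) at 0.15 (33 of 60 higher, 1 lower). The other families past these limits were ADAMTS (-0.29), PDE (-0.28) and RNF (-0.11) on the lower side, and AKR (0.57), CD (0.19), DDX (0.16) and HOXB (0.30) on the higher. Some families overlap the lists given earlier and are not separate from them. The HOXB family restates the HOXB list, RPL genes are part of the ribosomal protein list, and WNT3 and WNT5B, both lower, belong to the primitive streak list.

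The MEIS1 level in the library labelled deleted was the first pattern weighed. The tables argue against reads divided between MEIS1 and other genes as its source. The 68 expected counts of MEIS1 there, like the 89 in wild type, were whole numbers, whereas divided reads leave fractions. Reads that fit another gene but were given wholly to MEIS1 would not be seen this way. An exchange of both labels stayed open. The interval of the MEIS1 fold, with an upper bound of 1.05, reached both sides of 1. A level clearly below or above 1 could not have settled it either, because the labels did not state the deleted part. An edit that leaves the transcript in place, which the labels neither state nor exclude, stayed open as well and untested, since a single value per gene does not show which exons were read. Reads along MEIS1 may settle both.

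The second pattern was the lower pluripotency and primitive streak lists beside the higher lists of haemato-endothelial transcription factors and endothelial markers. The tables argue against GC content and gene length as the cause: after their trends were removed the medians of the pluripotency, streak, haemato-endothelial and endothelial lists were -0.56, -1.36, 0.92 and 0.75, at percentiles 0, 0, 100 and 100. A gained or lost chromosome is set aside by chromosome medians of at most 0.068 in size, where 3 copies against 2 would give 0.585. The lists stood apart after each chromosome was centred, but medians this small could not have moved them far, so this added no support. A difference between the cultures unrelated to genotype cannot be told apart from MEIS1 loss with 1 library per genotype. Whether either would act through a faster passage from streak to endothelium was not tested, and replicate cultures of each genotype over a time course would be needed to decide it.

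The third pattern was the mirror values of BMS1P2 and gene 414216, with 214 and 1 counts in wild type against 1 and 213. Reads shared between near-identical copies are a likely source: both had the same length, 4704 nucleotides, and expected counts that were not whole. Their summed counts differed by a log2 ratio of -0.024 (-0.30 to 0.26), which restates the mirror values and adds no separate support. Shared reads that leave fractions were not the source of most 2-fold calls. Of those 841 genes, 37.5% had a count that was not whole, against 34.2% of all genes compared. Reads given wholly to 1 of several genes would not be seen this way. The share was 33.1% among higher genes and 41.8% among lower ones. No biological explanation was tested for this pair.

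Gene lengths in the tables are averages weighted by isoform, and they differed little between libraries. Of 5480 genes with at least 200 counts in both, 0 differed by over 25% and 98.0% by under 5%. RUNX1, singled out after its values were seen and outside that set with 109 counts in wild type, had a weighted length of 7177 nucleotides in wild type and 6079 in the library labelled deleted.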
